A study of Mus musculus with 9 samples.

How the data were processed

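RNA of thymic iNKT cells from 5 Utx wildtype and 4 Utx knockout mouse samples was measured on an Affymetrix-type mouse expression array with 45101 probe sets. Per the labels' protocols, cells were sorted into a phenol-based reagent, total RNA was purified on columns, and the RNA was reverse transcribed, amplified with a kit for picogram amounts and labelled with biotin. The gate of the sort is not given in the sources used here. The deposited values are log2 expression levels, 1 per probe set and array, made by the authors with RMA (background correction, quantile normalization and summary of the probes of each probe set), per the submitters' processing notes, which give no version. RMA alone leaves nearly equal distributions on all arrays, whereas the interquartile ranges here ran from 3.45 to 4.29 (log2), and whether a further step followed is not given in the sources used here. Amplification from small amounts of RNA and the summary of probes can compress differences. Arrays give no read depth, and the number of arrays limits the precision.

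Probe sets were named through the array's annotation table. Of all probe sets, 34945 had 1 gene, 932 several, 9160 none and 64 were controls. 34754 of those with 1 gene matched the reference gene table through their Entrez identifier, and 0 symbols changed. Probe sets with several genes or none were named for no gene. For each of 18193 genes, the probe set with the highest mean over all arrays was used, and genes were tested when this mean was above the 25th percentile of all probe sets (4.54, log2), which left 14520. No 2 arrays of a group were duplicates: the smallest SD of the difference between 2 arrays of a group was 0.29 (log2). No coordinates are given, since the array files name no genome build.

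The groups, replicate numbers and batches came from the sample titles. The comparison of knockout with wildtype used limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on the log2 values of all 9 arrays, genotype and batch (3 levels) as fixed factors, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The difference is thus taken within batches 1 and 2, and batch 3 adds to the estimate of the spread only. Residual degrees of freedom were 5 and prior ones 3.50. An adjusted p in the text is from this limma test, or from camera where a list is meant. Errors are the SE of the fitted log2 difference or the SD between arrays of a group.

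The 30 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. Of 17 lists called, 8 were higher and 9 lower. With an estimated correlation 0 were called, the lists with an unadjusted p under 0.05 being NKT1 genes (p = 0.0429), G2 and M phase genes (p = 0.0489) and natural killer receptors (p = 0.0098), while fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, called 12. The 5 it did not call were NKT17, interferon-stimulated, cytokine and chemokine, cytokine receptor and B cell genes. Some members are in several lists: 11 of the 20 natural killer receptors, 5 of the 16 granule genes and 5 of the 19 cytokine genes are also NKT1 genes, and 2 of the 17 double-positive thymocyte markers each are also in the NKT2, precursor and conventional T cell lists.

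The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Kdm6a, the 12 genes of largest rise and the 12 of largest fall among called genes of equal sign in batches 1 and 2, up to 4 members of smallest p for each list described by gene, and Zbtb16, Tbx21, Gata3, Il2rb, Ifng, Il4, Klrb1c, Uty and Kdm6b whatever their result. An item that the rule also covers is not reported here. Chosen after the values were seen were which lists to describe by gene (those camera called or with at least 3 called members), the fits without the batch 1 pair, the test of whether the genotype difference varied by batch, the simulated batch adjustment, and the naming of Il12rb1, Runx3, Myb, Hoxa5, Col1a1, Kdm5c, Eif2s3y, Kdm5d, S100a8, S100a9, Lcn2, Ltf, Igkv6-15 and Igkv6-20. These genes were not among those refitted without single arrays, apart from their part in the lists.

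Alternatives covered the batch term, the replicate number as a block, the filter, the scaling, the choice of probe set, the eBayes settings, array weights, thresholds, and leaving out each of the 9 arrays in turn. Leaving out WT1 or KO1 gives the same fitted difference, because the other array is then alone in its batch. The limma fit was tested on simulated data with the spread of the real genes, batch shifts of 0.5 (SD, log2) and 200 changed genes among 14520: it recovered 2.99% of genes changed 1.5-fold, 31.3% of those changed 2-fold and 95.5% of those changed 4-fold, with 3 false among 89 calls. A camera test of 100 random lists gave 4% with p under 0.05. Genes were drawn independently in these simulations, so this share does not test camera on genes that move together. In 5 further simulated datasets without a genotype difference, batch shifts were removed by an empirical Bayes location and scale adjustment that kept genotype. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.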

Results

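Gene expression was measured on 9 microarrays, each carrying RNA of invariant natural killer T (iNKT) cells sorted from the thymus of mice aged 8 to 12 weeks. iNKT cells are T cells with a nearly fixed T cell receptor that recognises lipids presented by CD1d. In the thymus they mature from CD24-positive precursors into the NKT1, NKT2 and NKT17 subsets. The labels divide the arrays into 5 from Utx wildtype and 4 from Utx knockout animals, given as biological replicates. Utx, encoded by the X-linked gene Kdm6a, removes methyl groups from lysine 27 of histone H3. The question the labels and the title of the series pose is how the loss of Utx changes gene expression of iNKT cells. The titles also name 3 batches, which are not balanced over genotype: batch 1 holds 1 wildtype and 1 knockout array, batch 2 holds 1 wildtype and 3 knockout arrays, and batch 3 holds 3 wildtype arrays. Below, WT1 to WT5 and KO1 to KO4 stand for the wildtype and knockout replicates by their numbers in the titles. WT1 and KO1 form batch 1, and WT2 lies in batch 2 with KO2, KO3 and KO4.

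The median level per array lay between 5.97 and 6.09 (log2) and the interquartile range between 3.45 and 4.29. These ranges were mostly wider on knockout arrays (3.80 to 4.29) than on wildtype arrays (3.45 to 3.84). Levels correlated across genes at r = 0.978 to 0.992 between wildtype arrays, 0.978 to 0.987 between knockout arrays and 0.935 to 0.968 between arrays of different genotype. The main principal component, with 65.6% of the variance, separated the genotypes. KO2 had a score of 21.2 on it, the other knockout arrays had scores of 41.8 to 57.4, and the wildtype arrays lay between -39.8 and -29.9. The number of arrays limits the precision of every comparison.

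Kdm6a itself was examined ahead of all other genes. The probe set of highest level for Kdm6a read 9.97 ± 0.13 (log2, mean ± SD, n = 5) in wildtype and 9.94 ± 0.21 (n = 4) in knockout cells. Its difference was -0.01 (adjusted p = 0.977 by limma over all probe sets). The other 3 probe sets did not pass either, with differences of -0.46 (adjusted p = 0.235), 0.52 (adjusted p = 0.129) and -0.23 (adjusted p = 0.673). In batches 1 and 2 these differed by 0.15 and -0.86, by 0.59 and 0.46, and by 0.23 and -0.53. On the probe set at -0.46, KO1 to KO4 read 9.17, 8.94, 8.77 and 8.64, and the wildtype arrays 9.02 to 9.65. Array by array, the probe set of highest level read 9.94, 9.98, 10.15, 9.79 and 9.996 in WT1 to WT5 and 10.01, 9.62, 10.05 and 10.07 in KO1 to KO4. Which part of Kdm6a was deleted, and whether a probe set lies in it, is not given in the sources used here, so these levels do not check the genotype labels.

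In knockout iNKT cells, genes of mitosis and DNA replication were higher, while NKT1 effector genes, receptors shared with natural killer cells and cytotoxic granule genes were lower, by camera with a preset correlation. With an estimated correlation these 5 lists had adjusted p of 0.295 to 0.382, and on the same arrays double-positive thymocyte markers (median 1.35) and macrophage and dendritic cell markers (1.26) were higher. These markers were higher on the arrays behind every other list below as well. Bex1, of the brain-expressed X-linked family, had the largest rise, from 5.45 ± 0.48 (log2, mean ± SD, n = 5) to 9.65 ± 0.75 (n = 4), 18.9-fold (log2 difference 4.24, SE 0.51, adjusted p = 0.0041). Csf1r, the receptor for macrophage colony-stimulating factor, rose from 4.55 ± 0.71 to 8.61 ± 0.61 (log2 difference 4.05, SE 0.55, adjusted p = 0.0054), a call that ended without WT2 (3.18, adjusted p = 0.0584). Its wildtype mean lies at the level of the filter on low values (4.54), with WT2 at 4.08 and WT5 at 3.57. Whether the wildtype signal is above background was not measured, so no fold is given for Csf1r, and the rank of Bex1 above it is not fixed. The wildtype mean of Bex1 lies above that filter but below the median level of every array, so its fold carries a like limit. Gpnmb, a transmembrane glycoprotein best known from myeloid cells, had the largest fall, from 9.17 ± 0.47 to 6.05 ± 0.37, 8.54-fold (log2 difference -3.09, SE 0.37, adjusted p = 0.0041). In all, 1634 of 14520 genes passed limma's adjusted p of 0.05 with batch as a factor, 1144 of them higher and 490 lower in knockout cells, and 4469 had an unadjusted p under 0.05. Of the 1634 genes, 828 were at least 2-fold higher and 307 at least 2-fold lower.

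The other genes of largest rise, by the rule fixed for naming genes, were Bex4 (3.53), Scara3 (3.41), Bcat1 (3.30), Pkig (3.18), Cenpf (3.17), Zdhhc14 (3.14), Xist (3.03), Tmcc3 (3.02), Coq8a (2.98) and Nt5dc2 (2.93; all log2 differences, adjusted p 0.0029 to 0.035). The wildtype means of Bex4 (3.95) and Scara3 (3.25) and the knockout means of Cpe (4.47) and Ndnf (3.75), both among the falls below, lie under the filter level of 4.54. The sizes and ranks of these 4 differences rest on levels not shown to be above background. Among the genes that rose, Bcat1 is the cytosolic branched-chain amino acid transaminase, Pkig an inhibitor of protein kinase A, Cenpf a kinetochore protein and Xist the long noncoding RNA of X inactivation. On the probe set used, Xist differed by 5.27 in batch 1 and 1.54 in batch 2. Its other probe sets did not pass (2.36 and 2.24, adjusted p = 0.1163 and 0.1595 by limma over all probe sets). The other genes of largest fall were Tktl1 (-2.80), S100a6 (-2.65), Klrk1 (-2.62), Cpe (-2.59), Ctla2b (-2.59), Cd9 (-2.57), Klra5 (-2.54), Cdh1 (-2.51), Ndnf (-2.50), Ctla2a (-2.45) and Qpct (-2.44; adjusted p 0.0029 to 0.0146). Klrk1 encodes the activating receptor NKG2D, Klra5 the receptor Ly49E, Cd9 a tetraspanin and Cdh1 E-cadherin. Without WT1 or KO1 a fit keeps the difference within batch 2, and without WT2 that within batch 1, so that Ndnf moved to -1.53 and -3.96. Of these 24 genes, 3 lost their call when 1 array was left out: Csf1r without WT2 (3.18, adjusted p = 0.0584), Tmcc3 without WT1, WT2 or KO1 (2.67 to 3.55, adjusted p 0.0596 to 0.0687) and Xist without WT1, WT3, WT4, WT5, KO1 or KO3 (1.54 to 3.03, adjusted p 0.0525 to 0.0783).

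Over all genes tested, 65.3% had the same sign within batch 1 and within batch 2. All 1634 called genes did, which their selection by the difference pooled over these batches nearly fixes. Across genes, which are not independent replicates, the differences in batch 1 and in batch 2 correlated at r = 0.476 (Spearman's rho 0.461). Simulated values without a genotype difference, adjusted for batch with genotype kept, gave r of 0.0751 to 0.0897 and 51.2% of genes with the same sign. The simulated genes were drawn independently, so these values do not show what genes that move together would give. Bex1 was higher by 4.35 in batch 1 and by 4.16 in batch 2, Csf1r by 3.18 and 4.64, and Gpnmb lower at -4.20 and -2.36. In batch 2 alone, where the lone wildtype array is assumed to vary like the others, limma called 0 genes, with 3671 at an unadjusted p under 0.05, and 2185 genes without KO2. Batch 1, with 1 array per genotype, has no replicate check.

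The count of called genes depended on single arrays: it was 969 without WT2, 1033 without WT3, 1080 without WT4, 983 without WT5, 860 without KO3, 1069 without KO4 and 2054 without KO2. It was 10044 with batch as a random block, 6341 with no batch term, 340 without the 3 wildtype arrays of batch 3, and 1737, of which 962 were shared, without the batch 1 pair. Higher genes made up 70.0% of the calls on the values as deposited and 58.3% after another quantile normalization (1043 higher and 745 lower), where the median difference of all genes was 0.03 in place of 0.11. Without WT2 they made up 56.8% (550 higher and 419 lower), with a median of -0.01 over all genes. With no filter on low values they made up 65.3%, and with a filter at the 50th percentile 74.0%. The medians over all genes were then 0.04 and 0.20. The excess of higher genes thus depended on the level filter and the scaling, and the interquartile ranges differed between the genotypes too.

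**Figure D1:**
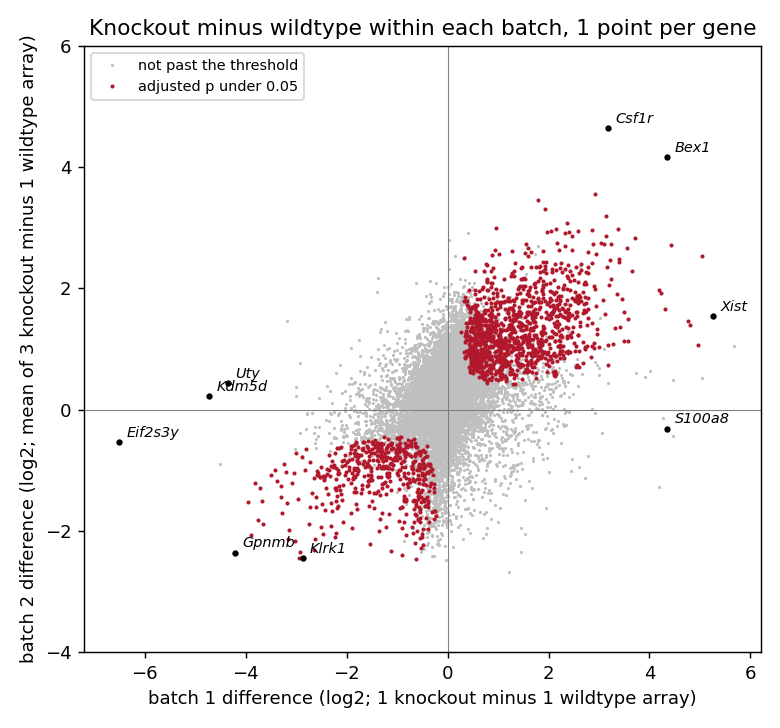
Each point is 1 gene; the horizontal axis gives its difference in batch 1 (log2, 1 knockout minus 1 wildtype array) and the vertical axis that in batch 2 (log2, mean of 3 knockout arrays minus 1 wildtype array), with the 1634 called genes in red and selected genes named. The called genes lie in the quadrants of equal sign, whereas Eif2s3y, Kdm5d, Uty and S100a8 lie far from 0 in batch 1 and near 0 in batch 2.

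NKT1 effector genes, which mark the T-bet-positive subset that makes interferon gamma, were lower in knockout cells. Of 28 members measured, 21 fell and 1, the chemokine gene Ccl4, rose (0.78, adjusted p = 0.0364), with 23 lower and 1 higher when adjusted over the list alone. The median difference was -1.30, 2.47-fold. The members of smallest p were Fcer1g (-1.62), a signalling chain of Fc and natural killer receptors, Klra5 (-2.54), the chemokine receptor gene Cxcr3 (-2.05) and Klre1 (-1.26; adjusted p 0.0045 to 0.0083). Ifng, the cytokine itself, fell from 10.46 ± 0.17 to 8.27 ± 1.03 (log2 difference -2.22, SE 0.57, adjusted p = 0.0418). Tbx21, which encodes T-bet, fell from 11.64 ± 0.13 to 10.55 ± 0.34 (log2 difference -1.08, SE 0.24, adjusted p = 0.0276), and Il2rb, a receptor chain for interleukins 2 and 15, from 12.19 ± 0.15 to 11.17 ± 0.26 (log2 difference -1.01, SE 0.21, adjusted p = 0.0231). The list was lower by camera with a preset correlation (adjusted p = 1.19e-14), with adjusted p = 0.382 with an estimated correlation. Its median was -1.36 in batch 1 and -1.05 in batch 2. On the same knockout arrays, markers of double-positive thymocytes, the CD4 and CD8 positive stage of T cell development, were higher by a median of 1.35, and those of macrophages and dendritic cells by 1.26. KO2 lay nearest to wildtype, with a median member 0.86 lower than the wildtype mean (log2 -0.86) against -1.43 to -1.24 on the other knockout arrays. The calls of 3 of these genes ended when 1 array was left out: Tbx21 without WT1, WT2, WT3, KO1, KO3 or KO4 (-1.26 to -0.96, adjusted p 0.0504 to 0.105), Il2rb without WT1, KO1 or KO3 (-0.99 to -0.76, adjusted p 0.0521 to 0.0802) and Ifng without WT1 to WT5 or KO1 (-2.74 to -1.88, adjusted p 0.0665 to 0.130). That of Ccl4 ended without WT2 to WT5, KO3 or KO4 (0.51 to 0.83, adjusted p 0.0521 to 0.448).

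Receptors shared with natural killer cells fell alongside. Of 20 measured, 12 fell (15 when adjusted over the list alone) and 1 rose, and 11 of the 20 are also in the NKT1 list. The median difference was -1.33, 2.51-fold. Klra8, which encodes the activating receptor Ly49H, went the other way, rising from 8.16 ± 0.23 to 9.98 ± 0.32 (log2 difference 1.84, SE 0.26, adjusted p = 0.0059), with 1.92 in batch 1 and 1.79 in batch 2. Klra genes are close relatives, and probe sets for them can cross-react. Klrb1c, which encodes NK1.1, has no result of its own, because its probe set is shared with Klrb1b. The list was lower by camera (adjusted p = 4.04e-10; adjusted p = 0.295 with an estimated correlation), with medians of -1.45 in batch 1 and -1.04 in batch 2.

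Cytotoxic granule genes were lower too. Among 16 members, 7 fell and 0 rose (9 and 0 adjusted over the list alone), with a median difference of -0.74. Cst7, which encodes the cathepsin inhibitor cystatin F, fell by 1.73 on the log2 scale, Serpinb9, an inhibitor of granzyme B, by 1.18, Gzmb, granzyme B, by 1.29, and Fasl, the Fas ligand gene, by 1.38 (adjusted p 0.0117 to 0.0167). Without WT2 the call of Gzmb ended (-1.29, adjusted p = 0.0948), and without WT1 or KO1 that of Fasl (-0.99, adjusted p = 0.0569). Camera gave an adjusted p of 1.26e-05 for the list, and adjusted p = 0.382 with an estimated correlation. The medians were -1.02 in batch 1 and -0.50 in batch 2.

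Cell cycle genes rose together. Of 24 genes of G2 and M phase, 23 rose and 0 fell (the same numbers adjusted over the list alone), with a median difference of 1.83, 3.54-fold. Hmmr, a spindle-associated hyaluronan receptor, rose from 7.55 ± 0.13 to 10.44 ± 0.39 (log2 difference 2.92, SE 0.26, adjusted p = 0.0024). Ndc80 of the kinetochore rose by 2.01, the cyclin gene Ccnb2 by 2.16, and Cdc20, an activator of the anaphase-promoting complex, by 2.57 (adjusted p 0.0024 to 0.0029). Of 24 S phase genes, 16 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.93, 1.90-fold. The replication licensing gene Cdc6 rose by 2.69, Prim1, a primase subunit, by 1.23, Rrm1, a ribonucleotide reductase subunit, by 1.21, and Cdc45, part of the replicative helicase, by 1.79 (adjusted p 0.0039 to 0.0096). All 8 of these genes kept their call in each of the 9 fits that left out 1 array. Camera gave adjusted p of 5.16e-17 for G2 and M phase and 1.48e-10 for S phase. For each list, adjusted p = 0.382 with an estimated correlation. Within batches, the medians were 2.38 and 1.49 (batch 1 and batch 2) for G2 and M phase and 1.05 and 0.81 for S phase. KO2 lay nearest to wildtype, at 1.38 for G2 and M phase against 1.82 to 2.08 on the other knockout arrays, and double-positive thymocyte markers, of which 17 of 17 had a positive difference, were also higher on these arrays.

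**Figure D2:**
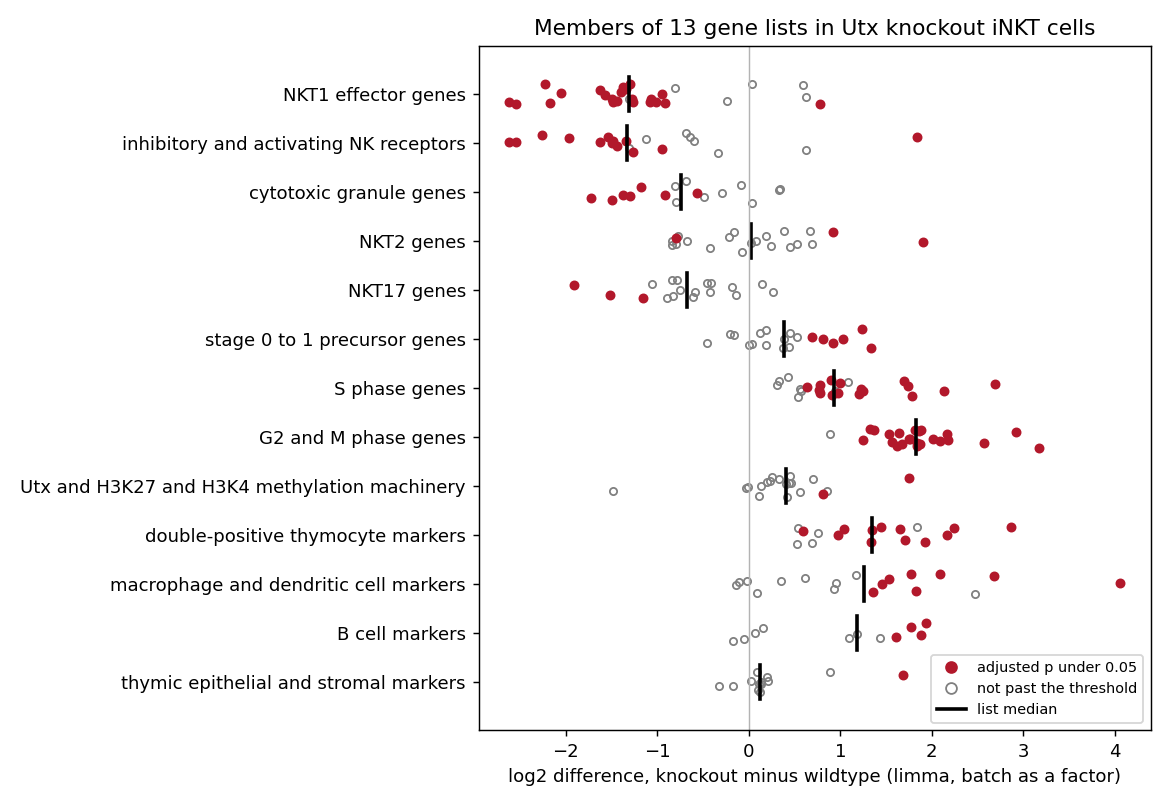
Each point is a gene of 1 of 13 lists, placed by its log2 difference (knockout minus wildtype, limma with batch as a factor); red points have an adjusted p under 0.05, open points do not, and black bars mark list medians. Mitotic genes lie at positive values (median 1.83), NKT1 genes mostly at negative ones (median -1.30), and NKT2 genes on both sides (median 0.03, and -0.15 after another quantile normalization).

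NKT2 genes mark the subset that makes interleukin 4, and NKT17 genes the subset that makes interleukin 17. Of 21 NKT2 genes, 2 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of 0.03 that turned to -0.15 after another quantile normalization. Camera gave an adjusted p of 0.571 with a downward direction, and the medians were -0.70 in batch 1 and 0.33 in batch 2. Ly6d (1.91) and the chemokine receptor gene Ccr7 (0.93) rose, and the transcription factor gene Maf fell (-0.80; adjusted p 0.0326 to 0.0461), while Cd4 had a difference of 0.69 (adjusted p = 0.0528). Il4, the signature cytokine of NKT2 cells, had a difference of -0.84 (SE 0.35, adjusted p = 0.144), with -1.96 in batch 1 and -0.09 in batch 2. Of 18 NKT17 genes, 3 fell (3 adjusted over the list alone) and 0 rose. Serpinb1a (-1.91), the integrin gene Itgb7 (-1.16) and the kinase gene Blk (-1.51) fell, with adjusted p 0.0265 to 0.0452. Il18r1 had -0.89 (adjusted p = 0.0867), with -1.76 in batch 1 and -0.31 in batch 2. This list was lower by camera (median -0.68, adjusted p = 1.94e-05; adjusted p = 0.382 with an estimated correlation), with medians of -1.46 in batch 1 and -0.25 in batch 2. Each of these 6 calls ended when some arrays were left out: Ly6d without WT1, WT5, KO1, KO3 or KO4 (1.07 to 1.99, adjusted p 0.0534 to 0.0896), Ccr7 with any but WT4 and KO2 left out (0.64 to 1.11, adjusted p 0.0531 to 0.484), Maf with any but KO2 (-1.13 to -0.58, adjusted p 0.0521 to 0.124), Serpinb1a without WT1, WT4 or KO1 (-1.91 to -1.44, adjusted p 0.0516 to 0.0893), and Itgb7 and Blk with any but WT2 and KO2 (-1.16 to -0.65, adjusted p 0.0571 to 0.111, and -1.61 to -0.64, adjusted p 0.0645 to 0.0829).

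Transcription factors of the iNKT lineage moved both ways. Of 24 measured, 3 rose and 3 fell (4 and 4 adjusted over the list alone), with a median of 0.02 that turned to -0.14 after another quantile normalization, and a mean of -0.03. Camera gave an adjusted p of 0.592 with a downward direction, and the medians were -0.17 in batch 1 and 0.12 in batch 2. Runx1, which acts early in iNKT development, rose from 8.84 ± 0.07 to 9.93 ± 0.06 (log2 difference 1.12, SE 0.14, adjusted p = 0.0045), with 1.03 in batch 1 and 1.18 in batch 2, and Myb rose by 0.69 (adjusted p = 0.0453). Hivep3 rose by 0.81 (adjusted p = 0.0234) on its probe set of highest level, but the mean of its probe sets gave -0.19 (adjusted p = 0.423), and the call ended without WT2 (0.47, adjusted p = 0.378) or KO3 (0.79, adjusted p = 0.0539). Tbx21 (values above, with the arrays whose omission ended its call), Runx3 (-1.25, adjusted p = 0.0384) and Klf2 (-0.81, adjusted p = 0.0367) fell. The call of Klf2 was kept only without KO2 or KO3 (-1.07 to -0.63, adjusted p 0.0504 to 0.119 elsewhere). Zbtb16, which encodes PLZF, the factor that defines the lineage, read 10.95 ± 0.19 in wildtype and 10.72 ± 0.21 in knockout cells (log2 difference -0.22, 95% interval -0.70 to 0.26, adjusted p = 0.510). Its difference was -0.72 in batch 1 and 0.12 in batch 2. Its 2 other probe sets had differences of -0.56 and -0.42 (adjusted p = 0.264 and 0.478 over all probe sets), with -1.41 and -1.51 in batch 1 and 0.01 and 0.31 in batch 2. Gata3, a factor of NKT2 cells, had a difference of 0.08 (SE 0.19, adjusted p = 0.809) and of -0.15 after another quantile normalization.

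Genes of newly selected CD24-positive iNKT precursors were higher as a list. Of 19 measured, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.38. After another quantile normalization this median was 0.20. Cd24a rose by 1.34, the transcription factor gene Sox4 by 1.24, Bcl6 by 1.03 and Hivep3 by 0.81 (adjusted p 0.0138 to 0.0301). Camera gave an adjusted p of 0.0338, and adjusted p = 0.382 with an estimated correlation. The medians were 0.36 in batch 1 and 0.34 in batch 2, and without either array of batch 1 the list was no longer called (adjusted p = 0.125). Cd24a is also a marker of double-positive thymocytes, and the markers of that stage were higher on the same arrays. Hivep3 had -0.19 with the mean of its probe sets, and its call ended without WT2 (0.47, adjusted p = 0.378) or KO3 (0.79, adjusted p = 0.0539). The call of Sox4 ended without WT1, KO1 or KO3 (0.76 to 1.204, adjusted p 0.0581 to 0.0821) and that of Bcl6 with any array but WT2 and KO2 left out (0.75 to 1.03, adjusted p 0.0545 to 0.104).

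Among 12 genes of thymic egress and recirculation, 7 fell and 1, Ccr7, rose (8 and 2 adjusted over the list alone), with a median of -0.83. The integrin genes Itga1 (-1.46), Itgb7 (-1.16) and Itgal (-0.67) and the sphingosine-1-phosphate receptor gene S1pr1 (-0.92) fell (adjusted p 0.0259 to 0.0358). Camera gave an adjusted p of 0.0032, and adjusted p = 0.382 with an estimated correlation. The medians were -1.23 in batch 1 and -0.51 in batch 2. On the same arrays, markers of double-positive thymocytes (median 1.35) and of macrophages and dendritic cells (1.26) were higher. These calls, too, ended when some arrays were left out: Itga1 and S1pr1 without WT1, KO1, KO3 or KO4 (-1.41 to -1.08, adjusted p 0.0511 to 0.0883, and -0.96 to -0.62, adjusted p 0.0501 to 0.0935), Itgb7 with any but WT2 and KO2 left out (-1.16 to -0.65, adjusted p 0.0571 to 0.111), Itgal with any but KO2 left out (-0.95 to -0.49, adjusted p 0.0540 to 0.122), and Ccr7 with any but WT4 and KO2 (0.64 to 1.11, adjusted p 0.0531 to 0.484).

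Of 27 cytokine receptors and signal relays, 4 fell and 1 rose (8 and 4 adjusted over the list alone). Il12rb2 (-1.39) and Il12rb1 (-1.22), the receptor chains for interleukin 12, Il18rap (-1.28), a chain of the interleukin 18 receptor, and Il2rb fell, and Ifngr2, a chain of the interferon gamma receptor, rose (0.85; adjusted p 0.0126 to 0.0409). The list was lower by camera (median -0.17, adjusted p = 0.0495; adjusted p = 0.602 with an estimated correlation), with medians of -0.40 in batch 1 and 0.06 in batch 2. The call ended without WT1, WT4, WT5, KO1 or KO4 (adjusted p 0.0511 to 0.354). Il2rb lost its call without WT1, KO1 or KO3 (-0.99 to -0.76, adjusted p 0.0521 to 0.0802), Il18rap without the same arrays (-1.25 to -0.83, adjusted p 0.0507 to 0.0687), and Ifngr2 with any array but WT4 and KO2 left out (0.78 to 0.87, adjusted p 0.0532 to 0.196). Of 19 cytokine and chemokine genes, Ifng and Xcl1 (-1.57, adjusted p = 0.0209) fell and Ccl4 rose (the same numbers adjusted over the list alone), with Tnfsf10 at -0.85 (adjusted p = 0.0742). Camera called this list lower (median -0.31, adjusted p = 0.0249; adjusted p = 0.610 with an estimated correlation), but its median was -1.13 in batch 1 and 0.18 in batch 2, and without either array of batch 1 it was not called (adjusted p = 0.656). Xcl1 also lost its call without WT1 or KO1 (-1.14, adjusted p = 0.0720), Ifng without WT1 to WT5 or KO1 (-2.74 to -1.88, adjusted p 0.0665 to 0.130) and Ccl4 without WT2 to WT5, KO3 or KO4 (0.51 to 0.83, adjusted p 0.0521 to 0.448).

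Interferon-stimulated genes were lower as a list, with 4 of 24 lower and 0 higher (6 and 1 adjusted over the list alone) and a median of -0.44. Usp18 (-0.90), Mx1 (-1.47), Rsad2 (-0.93) and Xaf1 (-1.03) fell (adjusted p 0.0167 to 0.0472). Camera gave an adjusted p of 9.25e-05, and adjusted p = 0.486 with an estimated correlation. The median was -0.93 in batch 1 and -0.03 in batch 2, where the 4 called genes had differences of -1.14 to -0.58. The difference of the list between batches was not tested. The list was not called without either array of batch 1 (adjusted p = 0.132). Usp18 lost its call without WT1, WT2 or KO1 (-1.0001 to -0.84, adjusted p 0.0528 to 0.0832), Mx1 without WT1, WT2, WT4, WT5, KO1 or KO4 (-1.97 to -1.14, adjusted p 0.0511 to 0.112), Rsad2 without WT1, WT3, WT4, WT5, KO1 or KO4 (-0.93 to -0.58, adjusted p 0.0684 to 0.144) and Xaf1 with any array but KO2 left out (-1.55 to -0.69, adjusted p 0.0535 to 0.166).

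Among 19 genes of the Utx and histone methylation machinery, 2 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.41. After another quantile normalization this median was 0.22. Ezh2, the methyltransferase that places the mark Utx removes, rose from 10.34 ± 0.17 to 12.07 ± 0.29 (log2 difference 1.75, SE 0.23, adjusted p = 0.0048), 3.36-fold, with 2.18 in batch 1 and 1.47 in batch 2. Dpy30, a subunit of histone H3 lysine 4 methyltransferase complexes, rose by 0.82 (adjusted p = 0.0418), a call kept only without WT1 or KO1 (0.47 to 0.85, adjusted p 0.0537 to 0.547 elsewhere). Kdm6b, the related demethylase, had a difference of 0.42 (SE 0.14, adjusted p = 0.0899), Paxip1 of 0.86 (adjusted p = 0.0535) and Rbbp5 of 0.44 (adjusted p = 0.0863). The other probe sets of Kdm6b, of lower level, had -0.19 and 0.36 (adjusted p = 0.693 and 0.253 by limma over all probe sets). The difference of Paxip1 was 0.37 in batch 1 and 1.19 in batch 2. Uty, the Y-linked relative of Utx, had a difference of -1.48 (SE 0.87, adjusted p = 0.277), with -4.36 in batch 1 and 0.43 in batch 2, on its probe set of highest level. Of its 3 other probe sets 1 fell (-1.94, adjusted p = 0.0255 over all probe sets), and 2 had differences of -2.52 and -1.998 (adjusted p = 0.0609 and 0.0527). In batch 2 these 3 had -1.20, -1.07 and -0.94. Camera called the list higher (adjusted p = 0.0126; adjusted p = 0.486 with an estimated correlation), with medians of 0.24 in batch 1 and 0.43 in batch 2, and not without WT2 (adjusted p = 0.170). On the same arrays, genes of G2 and M phase (median 1.83) and double-positive thymocyte markers (1.35) were higher as well. Developmental targets of Polycomb repression were not called (median 0.15, adjusted p = 0.592 by camera): of 17 measured, Hoxa5 rose (2.22, adjusted p = 0.0046, and 1 adjusted over the list alone) and 16 did not pass. The list holds 36 genes, and only 3 of the 17 measured lie above the array median in wildtype cells. Genes this low can hardly fall further, so the list cannot decide whether such targets were lowered.

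Signalling, survival and glycolysis lists were not called by camera, though single members moved. Of 28 T cell receptor and SLAM signalling genes (median -0.08, camera adjusted p = 0.166), Lag3 (0.93) and Nr4a3 (0.88) rose and Malt1 (-1.005) fell (adjusted p 0.0200 to 0.0270; 3 and 3 adjusted over the list alone). Of 16 BCL2 family and apoptosis genes (median -0.04, mean 0.21, adjusted p = 0.881 with a downward direction), Pmaip1 (1.70), Birc5 (1.25) and Bcl2l1 (1.13) rose and Fasl fell (adjusted p 0.0099 to 0.0179; 3 and 1 adjusted over the list alone). Birc5, survivin, is also in the G2 and M phase list. Of 17 glycolysis genes (median 0.02, and -0.08 after another quantile normalization; adjusted p = 0.967), Hk2 (0.99) and Pfkm (0.80) rose and Slc2a3 (-0.61) fell (adjusted p 0.0135 to 0.0419; 4 and 1 adjusted over the list alone). Pmaip1 and Birc5 kept their calls whichever array was left out. Those of Malt1 (-0.83, adjusted p = 0.217) and Hk2 (1.04, adjusted p = 0.0834) ended without WT2, those of Bcl2l1 (0.90, adjusted p = 0.0647) and Fasl (-0.99, adjusted p = 0.0569) without WT1 or KO1, that of Lag3 without WT1, WT2 or KO1 (0.89 to 0.999, adjusted p 0.0578 to 0.113), that of Nr4a3 with any array but WT4 and KO2 left out (0.72 to 1.13, adjusted p 0.0504 to 0.0892), that of Slc2a3 likewise (-0.72 to -0.54, adjusted p 0.0511 to 0.119) and that of Pfkm with any but KO2 (0.74 to 0.89, adjusted p 0.0584 to 0.192). In the lists of oxidative phosphorylation (26 genes, median 0.21, adjusted p = 0.0838), cytosolic ribosomal proteins (18, -0.08, 0.142) and immediate early and heat shock genes (21, 0.12, 0.881, with a downward direction by camera), 0 genes passed limma, also adjusted over each list alone.

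Markers of other cells of the thymus differed between the genotypes. Of 17 double-positive thymocyte markers, 12 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.35: Arpp21 rose from 8.81 ± 0.17 to 11.01 ± 0.37, Ptcra, the pre-T cell receptor alpha gene, from 8.63 ± 0.18 to 10.76 ± 0.37, Mns1 from 8.55 ± 0.49 to 11.39 ± 0.54 and Aqp11 from 9.11 ± 0.21 to 10.995 ± 0.42 (adjusted p 0.0038 to 0.0079). Camera called the list higher (adjusted p = 4.33e-09; adjusted p = 0.382 with an estimated correlation), with medians of 1.96 in batch 1 and 0.92 in batch 2. Of 18 macrophage and dendritic cell markers, 8 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.26. Csf1r (above) and the antigen presentation genes H2-Ab1 (2.09), H2-Aa (1.83) and Cd74 (1.36) had the smallest p (adjusted p 0.0029 to 0.0118). Camera gave this list an adjusted p of 9.25e-05, and adjusted p = 0.382 with an estimated correlation. Its medians were 1.99 in batch 1 and 0.75 in batch 2. Of 11 B cell markers, Spib (1.94), Ighm (1.88), Cd79a (1.78) and Cd79b (1.605) rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p 0.0111 to 0.0181), with a list median of 1.18 (camera adjusted p = 0.0107; adjusted p = 0.538 with an estimated correlation), 1.58 in batch 1 and 0.76 in batch 2. Without WT2, Csf1r (3.18, adjusted p = 0.0584) and all 4 of these B cell genes lost their calls (the B cell genes at 1.59 to 2.09, adjusted p 0.0574 to 0.147). Without either array of batch 1, neither the macrophage (0.75, adjusted p = 0.0903) nor the B cell list (0.76, adjusted p = 0.301) was called.

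Of 10 conventional T cell markers, Cd8b1 (1.35), Cd8a (0.98) and Ccr7 rose and 0 fell (5 and 1 adjusted over the list alone). Dapl1 had -0.80 (adjusted p = 0.0730), with -0.29 in batch 1 and -1.14 in batch 2. The list median was 0.58, with 0.59 in batch 1 and 0.38 in batch 2. Camera called the list higher (adjusted p = 0.0495, and adjusted p = 0.382 with an estimated correlation). This list was not called without WT1, WT5, KO1, KO2 or KO4 (adjusted p 0.0574 to 0.420), nor was Cd8b1 without WT1 or KO1 (0.80, adjusted p = 0.0660), Cd8a with any array but WT2 and KO2 left out (0.62 to 1.01, adjusted p 0.0524 to 0.1004) or Ccr7 with any but WT4 and KO2 (0.64 to 1.11, adjusted p 0.0531 to 0.484). Gamma delta T cell markers were lower: of 3 measured, Trgv4 fell (-0.93, adjusted p = 0.0265) and Sox13 and Cd163l1 had differences of -1.07 and -1.06 (adjusted p = 0.0714 and 0.0956; 3 lower adjusted over the list alone), with medians of -1.84 in batch 1 and -0.56 in batch 2. Camera called this list lower (adjusted p = 0.0070; adjusted p = 0.382 with an estimated correlation), but not without either array of batch 1 (adjusted p = 0.0903), and Trgv4 lost its call without WT1, WT3, WT5, KO1 or KO3 (-0.93 to -0.68, adjusted p 0.0503 to 0.0923). Granulocyte markers were not called (7 genes, median 0.91, adjusted p = 0.423; 1 higher adjusted over the list alone) and had medians of 2.39 in batch 1 and -0.31 in batch 2. Relative to the wildtype mean, their median was 1.98 in KO1, 0.78 in KO2, -0.27 in KO3 and 2.22 in KO4, and 0.71 in WT2. Erythroid markers (3 genes, median -0.06, adjusted p = 0.331) and stromal and epithelial markers (13 genes, median 0.12, adjusted p = 0.611) were not called. Among the latter Col1a1 rose (1.68, adjusted p = 0.0114; 1 higher adjusted over the list alone).

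**Figure D3:**
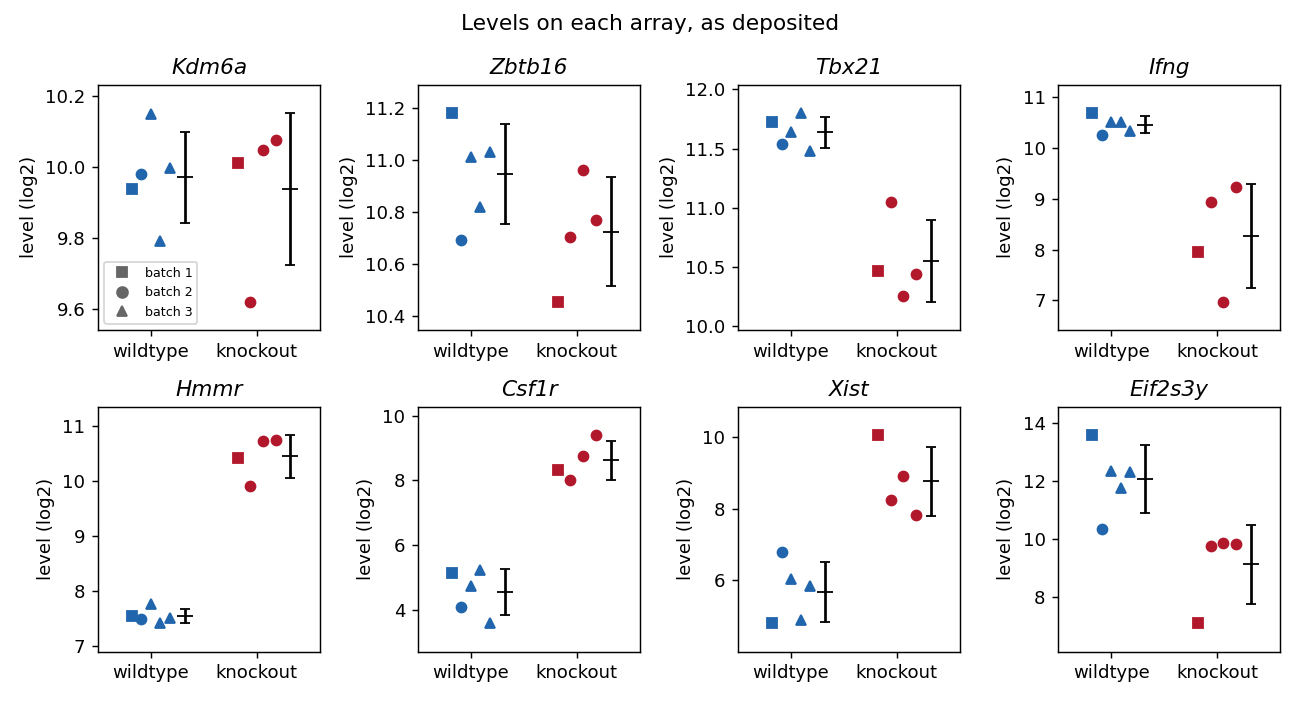
Levels (log2, as deposited) of 8 genes on each array, wildtype in blue and knockout in red, with squares, circles and triangles for batches 1, 2 and 3; the black mark beside each group is its mean with 1 SD (n = 5 wildtype, n = 4 knockout). Hmmr, Csf1r and Xist are higher on all 4 knockout arrays than on any wildtype array, and Tbx21, Ifng and Eif2s3y lower. Kdm6a and Zbtb16 overlap between genotypes. KO1 lies farthest from wildtype for Xist (10.07) and Eif2s3y (7.07).

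Transcripts linked to sex differed most in batch 1, although the labels call the animals sex-matched. Between KO1 and WT1, Xist was higher by 5.27 (log2) and the Y-linked genes Eif2s3y, Kdm5d and Uty had differences of -6.51, -4.72 and -4.36. In batch 2 the same differences were 1.54, -0.53, 0.22 and 0.43. These are the probe sets of highest level. On them, Xist read 7.84 to 10.07 on the knockout and 4.80 to 6.79 on the wildtype arrays, and Eif2s3y 7.07 to 9.84 and 10.32 to 13.58. For Kdm5d and Uty the genotypes overlapped. In batch 2 the other probe sets of the Y-linked genes had differences of -1.42 to -0.88, and those of Xist 0.36 and 0.17. The genotype difference varied by batch for each of these 4 genes when adjusted over the 7 sex markers tested (limma, adjusted p 4.55e-06 to 0.0026), and only for Eif2s3y over all genes (adjusted p = 0.0056). Kdm5c, an X-linked gene that escapes inactivation, rose on its probe set of highest level (log2 difference 1.03, adjusted p = 0.0113), with 0.95 in batch 1 and 1.09 in batch 2. Its other probe sets did not pass, with differences of -0.46 to 1.02. As a list, the sex markers had a mean of -0.25 and a median of 0.04, which turned to -0.06 after another quantile normalization (camera adjusted p = 0.967; 2 higher and 0 lower over all genes, 2 and 1 adjusted over the list alone). Over all genes, the genotype difference varied by batch for 3, with 1926 at an unadjusted p under 0.05. The batch 1 difference enters every fitted difference, so a difference of sex between WT1 and KO1 would be mixed with genotype in all calls.

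The batches themselves did not differ on the deposited values. With genotype in the limma fit, 0 genes were called for batch and 0 had an unadjusted p under 0.05, the median p being 0.979. Among the wildtype arrays alone, batch 3 against batches 1 and 2 gave 0 calls, 0 genes with an unadjusted p under 0.05 and a median p of 0.941. The deviations of WT1 from its group mean correlated across genes at r = -0.991 with those of WT2 and at r = -0.922 with those of KO1. In 5 simulated datasets with no genotype difference that were adjusted for batch with genotype kept, limma called 1437 to 1546 genes without a batch term and 0 with it, and even with it 9.73% of genes had an unadjusted p under 0.05.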

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

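The count of calls over other splits of the arrays was planned; all other tests in this part were chosen only after the result was seen.

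Of 218 groups of levels examined (each named gene in each genotype), 11 held an array far from the rest of its group, and chance gives about 1 in 20. KO2 was that array in 10 of them, nearer to the wildtype level in 9 of the 10. It read 9.94 for S100a6 (log2; 9.19 to 9.29 on the other knockout arrays), 11.11 for Bcl6, 10.55 for Itga1, 9.41 for Nr4a3, 8.83 for Cdc45, 9.02 for Ndc80, 7.92 for Pfkm, 10.46 for Arpp21 and 10.20 for Ptcra. For Kdm6a it read 9.62. WT4 was that array for Gzmb, at 11.98.

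The genotype difference in batch 1 exceeded that in batch 2 by 4.41 (log2) for Igkv6-15 and by 3.46 for Igkv6-20, both immunoglobulin kappa variable genes (limma, adjusted p = 0.0056 and 0.0373). Of 10092 probe sets with no gene or several genes, which the gene comparison leaves out, 615 were called for genotype, 214 of them higher and 401 lower in knockout cells.

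With the batch term, 1 of 100 splits of the 9 arrays into 5 and 4, the real one, called as many as 1634 genes. This share is under the bound of 5%, and the highest of the other splits called 21. Among the splits run, 6 others kept the number of arrays per genotype in each batch, and the highest of them called 0. Splits of this kind are too few for a share under 5%. Values adjusted with the real genotype kept would favour the real split, so these counts cannot exclude chance assignment. Simulated values of that kind without a genotype difference gave 0 calls with the batch term. Their genes were drawn independently, and the other splits were not run on them.

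No gene differed between batches, which is the pattern weighed here. Batches that did not differ, with no adjustment, would leave about 5% of genes with an unadjusted p under 0.05; the share was 0%, which argues against this. Values adjusted for batch with genotype kept before deposit may be the source: the deviations of WT1 and KO1 from their group means correlated at -0.92, and simulated values of this kind gave a mean r of -0.973 (r -0.922 in the data). No source used here states such a step, and no biological explanation was tested.

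The sex-linked transcripts differed by batch: the difference in batch 1 minus that in batch 2 was 3.72 for Xist, -5.97 for Eif2s3y, -4.94 for Kdm5d and -4.79 for Uty (log2). Loss of Utx acting alike on every knockout array is argued against by the median of the 3 Y-linked genes in batch 2, 0.22, against -4.72 in batch 1. Exchanged labels of the batch 1 pair are argued against by the correlation of the differences in batches 1 and 2, r = 0.48. Animals of different sex behind WT1 and KO1 may account for the pattern: 4 of the 4 genes differed by more than 2 in that direction. These genes are the pattern itself, so this count is no independent test. The other sex markers had 0.95 and 1.09 (Kdm5c), 0.32 and 0.27 (Ddx3x) and 0.23 and -0.09 (Eif2s3x) in batches 1 and 2. Their change between batches did not pass (limma, adjusted p 0.645 to 0.881 over the sex markers). If the sexes differed, sex and genotype would be confounded in batch 1, whose difference enters every fitted difference, that of the X-linked gene Kdm6a included. Other probe sets of Uty (-1.20, -1.07 and -0.94), Kdm5d (-1.19 and -0.88) and Eif2s3y (-1.42) were lower in batch 2 as well, while the 2 other probe sets of Xist had 0.36 and 0.17 there, against 1.54 on the one used. A difference in the makeup of batch 2 stays open.

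NKT1 genes were lower (median -1.30) while markers of double-positive thymocytes, macrophages and B cells were higher. Dilution of iNKT RNA by RNA of other cells as the whole cause is argued against by Zbtb16, over all arrays only on its probe set of highest level. Whether that probe set also reads other transcripts was not checked, which limits this argument. That probe set had -0.22 (95% interval -0.70 to 0.26). The 2 other probe sets of Zbtb16 had -0.56 (-1.26 to 0.14) and -0.42 (-1.23 to 0.40), which leaves out the NKT1 median by little. That median was taken without error, while the quartiles of the NKT1 genes were -1.51 and -0.94, so these 2 do not decide. The intervals may also be too narrow, since simulated batch-adjusted values without a genotype difference gave 9.73% of genes an unadjusted limma p under 0.05. Within batch 1 dilution as the whole cause stays open: the 3 probe sets had -0.72, -1.41 and -1.51, against an NKT1 median of -1.36, with 1 array per genotype. In batch 2 they had 0.12, 0.01 and 0.31, against -1.05. More double-positive thymocytes in the knockout sorts could add to it and stay open: their markers were higher by a median of 0.92 without the batch 1 pair, 16 of the 17 lie above the array median in wildtype cells too, and the sort gate is not given. More CD24-positive precursors stay open as well. Precursor genes that are not double-positive markers had a median of 0.37 (95% 0.03 to 0.69), against 0.67, the bound set for the median. This interval comes from resampling the 17 genes, not the arrays, so it does not measure the spread between arrays. A change of the NKT1 genes within the iNKT cells through loss of Utx cannot be told apart from these, because the shares of cell types in the sorts were not measured here.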

How the results depend on the processing

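The fits without the batch 1 pair, and those without a filter within batches, were chosen only after the result was seen. All calls shared between a setting with gene-level values and the 1634 had the same direction. The number of calls stayed within 1.5 times under no filter, a filter at the 50th percentile, centring, the mean of all probe sets, eBayes with trend and robust, and a 1.5-fold minimum (1480 to 2083). With each probe set tested by itself, 1841 genes had a called probe set, 1236 a higher and 608 a lower one, so some had both. Directions were not compared with the 1634 there. The changes below are in the number of calls. It rose to 6341 (4038 higher, 2303 lower) with no batch term and to 10044 (6166 and 3878) with batch as a random block, where the consensus correlation was -0.32. It fell to 340 (274 and 66) in batches 1 and 2 only, to 534 (408 and 126) with array weights and to 120 (94 and 26) with an ordinary linear model. Batch 2 only gave 0 calls by limma (0 higher, 0 lower), with 3671 genes at an unadjusted p under 0.05. An adjusted p of 0.10 gave 3033 (2019 and 1014), and another quantile normalization 745 lower. Lists were not run with the random block, which camera does not take.

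The replicate number does not pair the arrays: the deviations of same-numbered arrays correlated at -0.92, 0.09, 0.02 and 0.15. With the replicate block in place of batch 4290 genes were called (2816 and 1474), and with the replicate block together with batch limma called 0 (0 and 0). The causes of these changes were not tested, apart from the fewer arrays in fits that leave some out and the fewer residual degrees of freedom under the block.

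Of the lists, 0 were called with an estimated correlation and 9 without the batch 1 pair. Directions turned for called and uncalled values. The medians of 2 called lists turned without the batch 1 pair, as without either of its arrays: cytokine and chemokine genes from -0.31 to 0.18 (adjusted p = 0.656) and cytokine receptors from -0.17 to 0.058 (adjusted p = 0.354). Camera's direction stayed downward for both. Glycolysis genes had medians of 0.018 with no batch term, -0.014 and -0.020 with the replicate block in place of and together with batch, and -0.080 after quantile normalization. Gata3 had -0.034 with the replicate block together with batch and -0.15 after quantile normalization. For immediate early genes the test's direction turned with no batch term (median 0.12), no filter and fry (0.12), and without the batch 1 pair (0.16). It also turned for BCL2 family genes (-0.040, no filter and fry), for iNKT regulators (0.02) and NKT2 genes (0.030) under fry, and for sex markers (0.070) with the mean of probe sets. Without the batch 1 pair Zbtb16 had 0.12, Uty 0.43, NKT2 genes 0.33, granulocyte markers -0.31 and stromal markers 0.021. Hivep3, which was called, had -0.19 with the mean of its probe sets. With the mean of all probe sets, 81 of 90 called named genes kept their call, 8 lost it and 1, Hivep3, turned. In batches 1 and 2 only, 40 of the 92 called named genes kept their call and 52 lost it. Without the batch 1 pair 59 kept it and 33 lost it.

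Leaving out each array in turn gave 860 to 2054 calls, 550 to 1508 higher, 249 to 574 lower, and 9 to 19 lists; within batch 2 it gave 0 to 2185, the latter without KO2, with a lone wildtype array assumed to vary like the others. The differences ranged from -0.067 to 0.077 for Kdm6a, -0.30 to 0.33 for Gata3, -0.72 to 0.12 for Zbtb16 and -4.36 to 0.43 for Uty. Medians ranged from -1.13 to 0.18 for cytokine and chemokine genes, -0.40 to 0.058 for cytokine receptors, -0.17 to 0.12 for iNKT regulators, -0.70 to 0.33 for NKT2 genes, -0.086 to 0.15 for BCL2 family genes, -0.13 to 0.12 for glycolysis genes, -0.020 to 0.27 for sex markers, -0.31 to 2.39 for granulocyte markers, -0.053 to 0.16 for immediate early genes and 0.021 to 0.47 for stromal markers. Of 92 called named genes, 48 were called in all 9 of these fits and 44 were not in at least 1. Signal over background is not given by the values used here, so how far dim probe sets limit a difference was not measured.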

Other observations

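The tests in this part were chosen only after the result was seen. Values of granulocyte genes are given here by batch. S100a8 and S100a9, which encode the subunits of calprotectin, were higher in KO1 than in WT1 by 4.36 and 4.20 (log2), while in batch 2 their differences were -0.31 and -1.28. Lcn2 had 2.39 and 1.29, and Ltf 1.12 and 0.36, in batches 1 and 2. The genotype difference did not pass limma's test for a change between batches for any of the 7 granulocyte genes (adjusted p 0.274 to 0.697), and 2 had an unadjusted p under 0.05.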
